A study of Mus musculus with 12 samples.

How the data were processed

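The assay was a pooled CRISPR screen in mouse CD8+ T cells of the C57BL/6 strain. Each lentiviral construct carried 4 sgRNAs in tandem and mKate2 marked transduced cells. Per the labels' protocols, transduced cells were transferred into tumour-bearing mice on day 12 after tumour inoculation, and CD8+mKate2+ tumour-infiltrating lymphocytes (TIL) were sorted on day 7 after transfer. Between 20000 and 40000 such cells came from each tumour, cells of 3 to 4 mice were pooled into a replicate, and the T cells were mixed at 1 to 50 with carrier cells of the human Raji line before DNA extraction. A frozen part of the transduced cells served as the starting reference (SR). The SR read-out used direct PCR and the TIL read-out used a PCR in 2 steps, so the amplification differed between the conditions being compared.

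Each of the 3 SR and 3 TIL replicates was read out over 2 regions of the construct, which gives 12 samples in 4 groups. Region 1 held the spacers of sgRNA 1 and sgRNA 2, and region 2 those of sgRNA 2 and sgRNA 3. The regions are read-outs of the same DNA, so they were averaged and counted as 1 replicate. The column names of the SR libraries carry the condition and region but no replicate number. They were numbered by the table that sets them beside a TIL library.

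The deposited scores are reads per construct that the authors multiplied by a factor of the library and rounded to whole numbers; they are called scaled reads here. The factor is not given in the sources used here. It was recovered from the low values as the step between them, which ran from 1.36 to 9.34 scaled reads per read, and between 97.9 and 100% of the values examined lay within 0.5 of a whole multiple of the step, against 10.7 to 64.1% by chance at the steps of the SR libraries and 36.7 to 73.5% at those of the TIL libraries, before allowing for the search for the step. Totals ran from 8288404 to 25646820 scaled reads per library. Because the values are scaled and rounded, tests built for raw counts were not used and the planned count test was replaced by limma on log2 values, the fallback fixed for normalized values. Per the submitters' processing notes, Bowtie2 was used, with no version and no role stated. No genome build is given in the sources used here, so no coordinates are printed; all 15 target symbols were found in the RefSeq gene table of the GRCm38.p6 assembly, which was used for names only.

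The deposited log2 columns are the authors' ratios of TIL over SR per region, and their mean. Recomputing them as log2 with 10 added to both values returned every one within 5e-05. The authors' deposited tables of constructs up 2-fold give, for each combination, the number of constructs with a log2 ratio of at least 1 in both regions and a log2 enrichment of that number over the library; recounting gave the same numbers for all 101 combinations in the 3 tables. The deposited enrichment was returned when 1 was added to each count, and it was 0 where no construct of a combination was up. A synergy score in the table for the third replicate was not used here because its definition is not given in the sources used here.

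The library had 690 constructs, and 1 line was emptied for this work, which left 689. They are 336 checkpoint constructs in 56 combinations, 180 co-stimulatory constructs in 30 combinations, 89 T cell receptor (TCR) signalling constructs in 15 combinations, and 84 non-targeting constructs. A combination had 6 constructs, except Cd247+Cd3e+Lat+Zap70 with 5. Combinations with fewer than 4 targets were filled up with non-targeting sgRNAs.

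Scaled reads were divided by the library total to give CPM and averaged over the regions, and log2(CPM + 1) was the value of a construct. Changes are therefore on the log2(CPM + 1) scale, which understates the loss of a construct that was not seen. No filter on low values was applied. A construct was called detected in a TIL replicate when it exceeded 1000 scaled reads in both regions. This threshold was chosen after seeing the data, in the gap between the abundant and the near-absent constructs of most TIL libraries. Region 1 of TIL 2 had no such gap, with 42 constructs between 50 and 10000 scaled reads, against 2 to 11 in the other TIL libraries. Constructs were compared between TIL and SR with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over 689 constructs. The value of a combination was the mean over its constructs minus the mean over the non-targeting constructs of the same sample; it was tested with limma over 101 combinations, and by a two-sided permutation test with 100000 draws against sets of non-targeting constructs, which adds the spread between constructs. Classes were compared with non-targeting sets, the number of targets was set against the combination value, and combinations with and without each target were compared within their class, each by two-sided permutation with 100000 draws (exact enumeration for TCR signalling targets). Construct lists were also tested with fry and camera. The excess of a combination over its single targets was tested with limma, and a bootstrap over constructs with 1000 draws gave its 95% interval. The permutation tests treat constructs or combinations as units, so their p-values describe this set of constructs in these 3 pools. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6; plots used matplotlib 3.10.9. An adjusted p under 0.05 counted as past the test.

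The labels do not say that the replicates came from separate cultures, so the p-values over replicates measure only the spread between these samples. The SR libraries differed from one another with a chi-square between 47.1 and 598 times its degrees of freedom. PCR reads without molecular identifiers are not independent molecules, so repeat PCRs of the same DNA could differ as much, and whether the SR replicates are separate samples stays open; they were counted as 3, as labelled. Their log2 levels correlated at 0.96 to 0.99, and those of the regions of an SR replicate at 0.91 to 0.98. Because reads are not independent molecules, binomial intervals (Wilson, 95%) cover counting error only.

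The combination tests were tested on simulated data, in which templates were drawn in proportion to SR abundance, as many as give the observed number of detected constructs, with 10 simulated sets and 11 combinations raised by each fold. Of combinations raised 8-fold, limma called 40.9% and the permutation test 62.7%; at 4-fold both called 14.5%, and at 2-fold limma called 1.82% and the permutation test 0%. Without any effect, limma called 0.198% of combinations and the permutation test 0%, while 13.0% and 7.13% fell under an unadjusted p of 0.05. The construct-level test of the same sets without effect called between 480 and 512 of 689 constructs lower and between 1 and 8 higher. Simulated TIL replicates were drawn independently, whereas TIL 1 and TIL 2 shared 29 detected constructs against 6.91 for independent lists. The simulated call rates therefore may not describe these data.

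Before the data were examined, the tests, the alternatives and the rule for naming items were fixed. Named are all 15 single-target combinations, up to 10 combinations past the combination-level limma test in each direction (the 5 of largest change where fewer than 5 pass), the 5 highest and 5 lowest excesses over the sum of single targets, and constructs at least 2-fold up in all 3 replicates or among the 5 most raised and 5 most lowered past the construct-level test. Of the 5 most lowered constructs, only their combinations and range are given. Construct lists fixed at the same time were the 3 classes and the combinations containing Pdcd1, Ctla4, both of these, Adora2a or Havcr2. Other items are named where a count is small, and were then chosen after their values were seen. Alternatives were other scalings, pseudocounts of 0.5 and 5, each region alone, medians, leaving out the lowest 10% of constructs by SR abundance, leaving out each replicate, and the replicate number as a block. Added after seeing the data were the authors' log2 values, detection as a read-out with and without adjustment for SR abundance by logistic regression, other detection thresholds, and TIL 1 and TIL 2 averaged to 1 value. A hypergeometric test of the 2-fold lists given the overlap of 2 replicates, and a permutation test without the constructs detected in both TIL 1 and TIL 2, were also added then. Alternatives fixed beforehand that need raw counts were not run.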

Results

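The screen asked which combinations of gene disruptions change the abundance of CD8+ T cells inside tumours. The targets were 6 inhibitory checkpoint receptor genes (Pdcd1, Ctla4, Tigit, Btla, Havcr2, which encodes TIM3, and Adora2a, which encodes an adenosine receptor), in 56 combinations of 1 to 4 genes. Both biological control classes covered genes that T cell activation uses: 5 co-stimulatory molecules (Cd28, Il2ra, Tnfrsf4, Tnfrsf9 and Tnfrsf18) in 30 combinations and 4 components of TCR signalling (Cd247, Cd3e, Lat and Zap70) in 15. The 84 non-targeting constructs were the negative control. Abundance was measured as scaled reads of each construct in 3 replicates of the starting reference and 3 replicates of tumour-infiltrating cells, over 2 regions each. Totals per library ran from 9963617 to 25646820 scaled reads in SR and from 8288404 to 23012713 in TIL.

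Most constructs present in the transferred cells stayed below the detection threshold of 1000 scaled reads in the tumours, a threshold chosen after the data had been seen. The median construct had between 10471 and 30999 scaled reads in the SR libraries and between 0 and 5 in the TIL libraries, where 107 to 545 of 689 constructs were at 0. Values below the threshold correlated with SR abundance (Spearman's rho between 0.13 and 0.68 in the 6 TIL libraries), with 0.61 and 0.13 in regions 1 and 2 of TIL 3. Whether these reads came from tumour cells was not tested, so it stays open whether undetected constructs were absent. In TIL, 78, 61 and 97 of 689 constructs were detected in replicates 1, 2 and 3, or 11.3% (Wilson interval 9.17 to 13.9%), 8.85% (6.95 to 11.2%) and 14.1% (11.7 to 16.9%). The 10 most abundant constructs took between 27.6 and 35.5% of the reads of a library, against 6.58 to 10.1% in SR. Detection followed starting abundance: in the lowest quintile of SR abundance 3.62, 2.90 and 0% of constructs were detected in replicates 1, 2 and 3, and in the highest quintile 23.9, 16.7 and 37.0%. Altogether 508 constructs were detected in no replicate, 132 in 1, 43 in 2 and 6 in all 3.

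**Figure D1:**
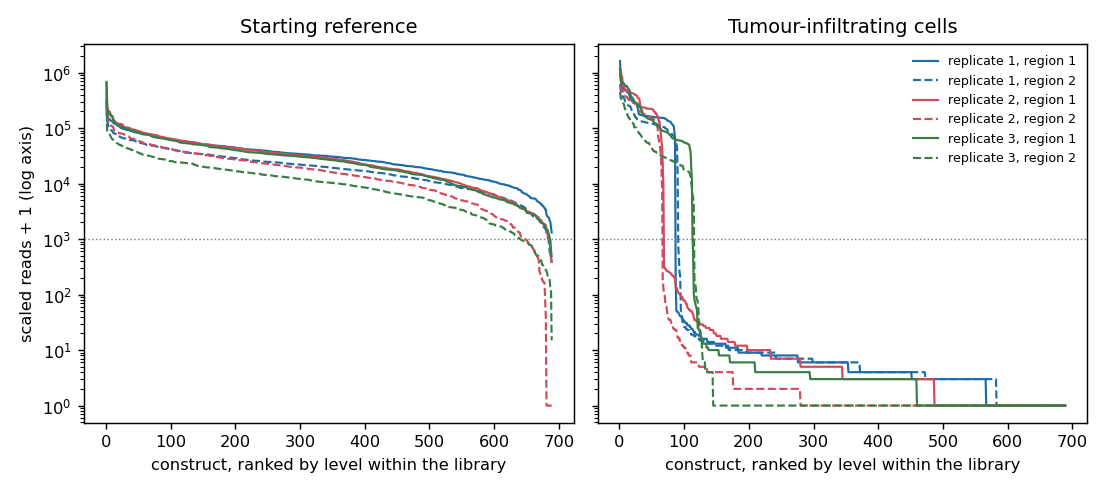
Scaled reads plus 1 (log axis) of the 689 constructs, ranked within each library, for SR (left) and TIL (right); colours mark replicates, solid lines region 1 and dashed lines region 2, and the dotted line is the detection threshold of 1000. SR levels decline gradually, while TIL levels drop steeply after 61 to 97 constructs detected in both regions. The exception is region 1 of replicate 2, where 42 constructs lie between 50 and 10000 scaled reads.

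The first comparison asked which single constructs changed between SR and TIL. Of 689 constructs, 467 fell and 3 rose (limma, adjusted p under 0.05). Scaled on the non-targeting constructs instead, 145 were lower and 32 higher than the non-targeting mean. That mean was itself -8.40 on the log2 scale, so these calls are not falls or rises against SR. The median change was -8.50 on the log2 scale, and -0.10 relative to the non-targeting mean. Fallen constructs were 68 of 84 in the non-targeting class, 65 of 89 in TCR signalling, 122 of 180 in the co-stimulatory and 212 of 336 in the checkpoint class. The strongest rise was in a construct against Il2ra, the alpha chain of the interleukin-2 receptor (spacer AGCCACGCTTGCTGATGTTG), with a log2 change of 2.74 ± 0.39 (SE, n = 3; limma adjusted p = 0.00172). This construct gave all 3 detections among the 18 cases of the Il2ra constructs. It was followed by a construct against Adora2a, Btla and Havcr2 (spacers CTCCACAAAGACCTGCGGCG, TTCATAGACCTAATGTGACT and AATCCCTTGCCCCAGCACAT) with 1.88 ± 0.20 (SE, n = 3; limma adjusted p = 0.000446). The third, against Adora2a, Btla and Pdcd1, had 1.59 ± 0.31 (SE, n = 3; limma adjusted p = 0.00600), but exceeded the detection threshold in both regions in replicate 3 only, and the authors' mean log2 ratio of its regions was -1.28, -2.83 and 1.35 in the 3 replicates. The most lowered constructs, against Zap70, Btla, Tnfrsf18, Cd247+Cd3e+Lat and Ctla4+Havcr2, lay between -12.08 and -11.70. In simulated sets without any effect of the targets, drawn independently for each replicate, between 480 and 512 constructs were called lower and between 1 and 8 higher. The fit scaled on non-targeting constructs was not run on these sets.

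Constructs at least 2-fold up in both regions, the authors' threshold, numbered 60, 52 and 42 in replicates 1, 2 and 3. The Il2ra construct and the Adora2a+Btla+Havcr2 construct above were the 2 that reached it in all 3 replicates. Independent lists would share 0.276 constructs, and a permutation of constructs within replicates reached 2 or more with p = 0.0331 (10000 draws), a test that takes the replicates as independent. At a 3-fold threshold the count was 0. Replicates 1 and 2 shared 20 such constructs, against 4.53 for independent lists, while replicates 1 and 3 shared 5 against 3.66 and replicates 2 and 3 shared 5 against 3.17. Given the constructs shared by replicates 1 and 2, chance overlap with the list of replicate 3 would give 1.22 in all 3 (exact hypergeometric test, unadjusted p = 0.348). From replicates 1 and 3 it would give 0.377 and from replicates 2 and 3 0.435 (same exact test, unadjusted p = 0.0482 and 0.0628). Checkpoint constructs were up 2-fold in 11.9, 9.23 and 6.55% of cases and non-targeting constructs in 4.76, 2.38 and 5.95%; none of the 9 class comparisons passed (Fisher's exact test, lowest adjusted p = 0.320). Among the authors' deposited values, Adora2a+Ctla4+Pdcd1 had the highest log2 enrichment of such constructs in each replicate. It was 3.02, 2.90 and 2.78, from 4, 3 and 2 of its 6 constructs, with 1 added to each count. In replicate 3 the combination shared the value of 2.78 with Cd28+Il2ra+Tnfrsf4, Ctla4 and Ctla4+Pdcd1.

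Repeatability across constructs was low. Pearson's r of the log2 TIL/SR ratio was 0.41 between replicates 1 and 2, -0.00093 between 1 and 3 and 0.057 between 2 and 3, with Spearman's rho of 0.64, 0.25 and 0.30, across 689 constructs that are not independent replicates. The regions of a replicate correlated at 0.82 to 0.88. SR levels of different replicates correlated at 0.96 to 0.99.

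The next comparison set each class against the non-targeting constructs. Checkpoint combinations lay above non-targeting sets: their mean log2 TIL/SR exceeded that of non-targeting constructs by 1.06 ± 0.51 (SD, n = 3), and was higher in 3 of 3 replicates (two-sided permutation over 56 combinations, adjusted p = 0.0181). Co-stimulatory combinations differed by 0.31 ± 0.12 (adjusted p = 0.425) and TCR signalling combinations by 0.18 ± 0.55 (adjusted p = 0.627; permutation, SD over n = 3), neither past the test. The class medians differed from the non-targeting median by 0.038 ± 0.11 for checkpoint, -0.30 ± 0.10 for co-stimulatory and -0.27 ± 0.31 for TCR signalling constructs (SD, n = 3), so that mean and median differed in sign for both control classes. With replicate 1 or replicate 2 left out, the checkpoint class no longer passed (permutation, adjusted p = 0.0619 and 0.0608). The same class as a construct list did not pass fry's directional test (adjusted p = 0.851, over all fixed lists). It did not pass camera either (adjusted p = 0.264, over all fixed lists). Camera compares a list with all other constructs, control classes included, and so asks a different question from the comparison with non-targeting constructs.

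Detection, a read-out added after the data had been seen, was also set against the non-targeting class. Checkpoint constructs were detected in 14.3 ± 2.87% of cases, co-stimulatory in 9.26 ± 1.70%, TCR signalling in 9.74 ± 4.54% and non-targeting in 6.35 ± 4.18% (SD, n = 3). The checkpoint class exceeded non-targeting by 7.94 percentage points, in 3 of 3 replicates (two-sided permutation, adjusted p = 0.0306). The co-stimulatory class differed by 2.91 points and TCR signalling by 3.28 points, in 3 and 2 of 3 replicates (permutation, adjusted p = 0.307 for both). When detection in either region sufficed, the co-stimulatory control class also passed, by 6.01 points in 3 of 3 replicates (permutation, adjusted p = 0.0400). After adjustment for starting abundance the checkpoint difference was 5.65 points and did not pass (permutation, adjusted p = 0.0900). Nor did the checkpoint difference pass without replicate 2 (7.59 points, permutation adjusted p = 0.0798).

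**Figure D2:**
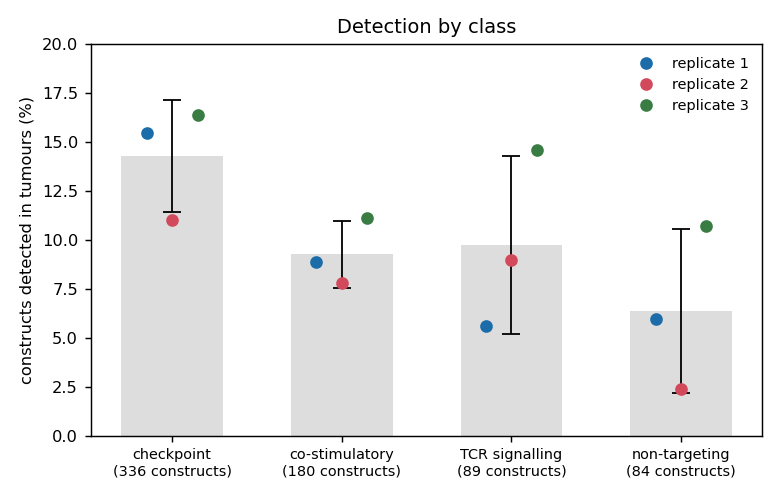
Percentage of constructs detected in TIL, by class; grey bars are means over 3 replicates, black lines ± 1 SD, and coloured points single replicates. Checkpoint constructs average 14.3% and non-targeting constructs 6.35%.

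The fixed construct lists were also tested as sets. Of the 26 combinations containing Pdcd1, which encodes the receptor PD-1, 24 lay above the non-targeting mean, with a mean of 1.41 on the log2 scale; the same held for 23 of 26 containing Adora2a (1.36), 20 of 26 containing Ctla4 (1.10), 22 of 26 containing Havcr2 (0.97) and 10 of 11 containing both Pdcd1 and Ctla4 (1.60). Most combinations lay above that mean, 72 of all 101 (0.70) and 45 of the 56 checkpoint combinations (1.06). The counts by themselves therefore cannot be credited to the listed genes. No list passed fry's directional test (lowest adjusted p = 0.293) or camera (lowest adjusted p = 0.264), and with an estimated correlation camera gave an adjusted p = 0.839 for every list. For change in either direction within a list, fry gave an unadjusted p between 5.35e-08 and 0.000899 over the 8 lists. The control classes were among these (0.000352 for co-stimulatory and 0.000899 for TCR signalling). No list of non-targeting constructs was tested, so these values cannot be credited to the targets. For the co-stimulatory and TCR signalling lists the camera direction was down although the mean was above 0. The mean is relative to non-targeting constructs, while camera compares a list with all other constructs. Single members past limma were 1 in each of the lists containing Pdcd1, Ctla4, Adora2a, and Pdcd1 and Ctla4, and 0 in the list containing Havcr2; adjusted over the list alone they were 3, 1, 1, 2 and 0, and for the checkpoint, co-stimulatory and TCR signalling classes 2, 0 and 0.

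Combination by combination, the joint disruption of Adora2a, Ctla4 and Pdcd1 stood highest. Adora2a+Ctla4+Pdcd1 rose relative to non-targeting constructs by 6.25 ± 1.03 on the log2 scale (SE, n = 3; limma adjusted p = 0.0387), with 7.22, 7.82 and 3.71 in replicates 1, 2 and 3. Its constructs were detected in 10 of 18 cases, against 16 of 252 for non-targeting constructs, and each of its 6 constructs was detected at least once. Averaged over replicates, the log2 TIL/SR of these 6 constructs lay between -4.62 and -0.54. The value of 6.25 is thus relative to mostly undetected non-targeting constructs and is not a rise over SR. None of the 6 passed by itself when scaled on non-targeting constructs (limma adjusted p between 0.249 and 0.490). In the permutation test against non-targeting constructs the combination had an adjusted p = 0.00101, which is the smallest that 100000 draws over 101 combinations can give. Without the replicate number as a block, it was the only one of 101 combinations past limma, where 19 had an unadjusted p under 0.05. With replicate 3 left out, 10 combinations were higher, and with medians over constructs 11 were higher and 37 lower. The limma call was lost without replicate 1 (5.77, adjusted p = 0.331), without replicate 2 (5.46, adjusted p = 0.202), with region 2 only (5.43, adjusted p = 0.185), when centred on all constructs (5.63, adjusted p = 0.0665) and with the authors' log2 values (6.39, adjusted p = 0.130). The permutation call held in the 15 alternatives tried, with adjusted p between 0.00101 and 0.0111.

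Without the replicate number as a block, the 4 combinations next in size did not pass limma. Adora2a+Ctla4+Havcr2+Pdcd1 had 4.08 ± 1.03 (SE, n = 3) and was detected in 8 of 18 cases, Adora2a+Btla+Ctla4 had 3.57 ± 1.21, Ctla4+Tigit 3.32 ± 1.65 and Pdcd1+Tigit 2.77 ± 0.58, with limma adjusted p of 0.153, 0.153, 0.343 and 0.0845. The first 3 of these passed the permutation test (adjusted p = 0.0101, 0.0452 and 0.0452), which made 4 combinations past it, all of them checkpoint combinations. All 4 contained Ctla4 and 3 contained Adora2a, which was seen after the calls. Of the 56 checkpoint combinations 26 contain Ctla4, and those with and without it differed by 0.086, not past the permutation test. Over the 15 alternatives the 3 combinations next in size passed the permutation test in 10, 3 and 2, with adjusted p up to 0.302, 0.584 and 0.913. Ctla4+Tigit lay below non-targeting constructs in replicate 3 (-0.78). All 3 of these calls were lost without replicate 1 and without replicate 2, when 1 combination, Adora2a+Ctla4+Pdcd1, passed. They were also lost when TIL 1 and TIL 2 were averaged to 1 value. These 2 replicates shared 29 detected constructs, against 6.91 for independent lists. Values at the lower end did not pass either test: Tnfrsf4+Tnfrsf9 had -1.60 ± 0.56 (SE, n = 3), Zap70 -1.50 ± 0.49, Cd28+Tnfrsf18+Tnfrsf4 -1.17 ± 0.79, Cd247+Cd3e+Lat+Zap70 -1.15 ± 0.53 and Il2ra+Tnfrsf4 -1.07 ± 0.52. In simulated sets drawn independently for each replicate, limma called 40.9% of combinations raised 8-fold and 14.5% of those raised 4-fold.

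Single-gene disruptions spanned both directions and none passed. Among the checkpoint genes, Pdcd1 alone had 2.62 ± 1.34 (SE, n = 3), with 3.10, 5.34 and -0.58 in the replicates, and was detected in 6 of 18 cases; Havcr2 had 1.77 ± 0.57 and was above 0 in 3 of 3 replicates. Adora2a had 0.75 ± 0.56, Ctla4 0.67 ± 0.86, Tigit -0.42 ± 0.60 and Btla -0.59 ± 0.53. Of the co-stimulatory genes, Il2ra had 1.36 ± 0.53, Cd28 0.93 ± 0.86, Tnfrsf18 0.31 ± 0.61, Tnfrsf9 0.083 ± 0.54 and Tnfrsf4 -0.079 ± 0.61. For Il2ra, all 3 detections in 18 cases came from 1 construct. Of the TCR signalling genes, Lat had 0.75 ± 0.88, Cd247 0.58 ± 0.94 and Cd3e 0.44 ± 0.74, and Zap70, a kinase required for TCR signalling, had the lowest value of the 15 genes.

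**Figure D3:**
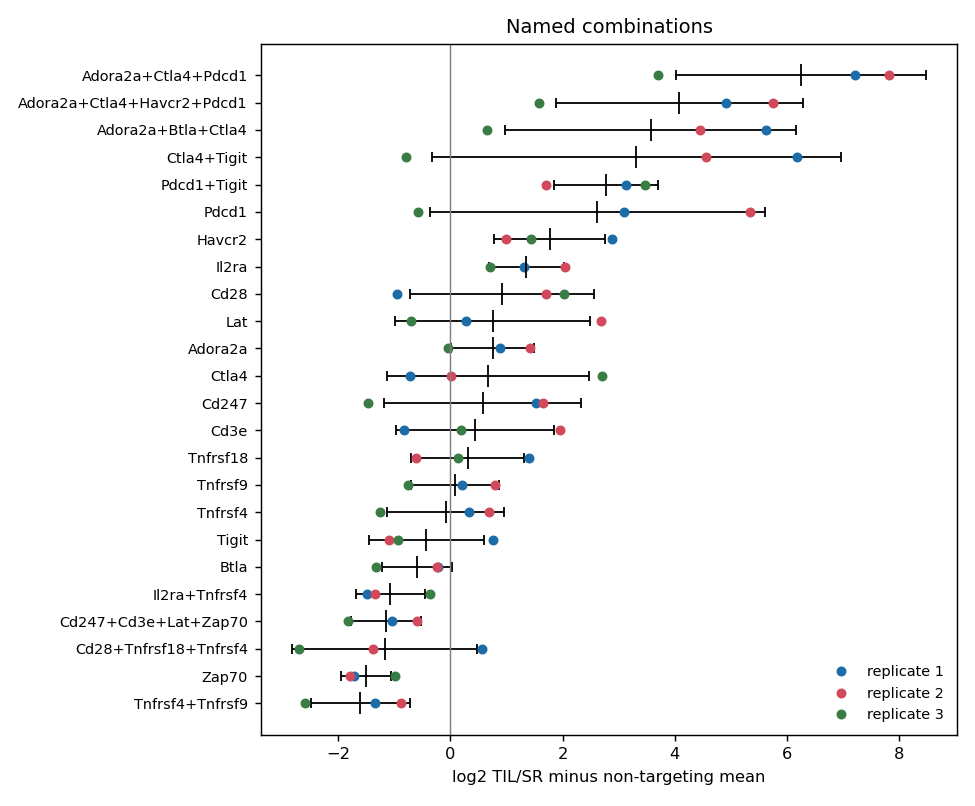
Log2 TIL/SR minus the non-targeting mean for the 5 highest and 5 lowest combinations and the 15 single genes; coloured points are replicates, black ticks means and lines ± 1 SD over 3 replicates. Adora2a+Ctla4+Pdcd1 has the highest mean, 6.25, with replicate 3 at 3.71.

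The number of targeted genes was not related to the value of a combination at this precision. Spearman's rho was 0.098 over the 56 checkpoint combinations, -0.25 over the 30 co-stimulatory and -0.15 over the 15 TCR signalling combinations (two-sided permutation, adjusted p = 0.598, 0.533 and 0.598). Checkpoint combinations of 1, 2, 3 and 4 genes averaged 0.80 ± 0.51, 0.86 ± 0.36, 1.27 ± 0.39 and 1.06 ± 0.85 (SD, n = 3), and were detected in 15.7, 11.9, 15.3 and 14.8% of cases. Co-stimulatory combinations of 1, 2, 3 and 4 genes averaged 0.52 ± 0.38, 0.47 ± 0.40, 0.26 ± 0.62 and -0.12 ± 0.30 (SD, n = 3). The slopes were 0.12, -0.21 and -0.034 log2 units per added gene in the 3 classes (permutation, adjusted p = 0.792, 0.687 and 0.917).

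Which gene a combination contained mattered past the test for 1 of the 15 targets. Co-stimulatory combinations containing Tnfrsf4, which encodes OX40, averaged -0.22 relative to non-targeting constructs and those without it 0.84. The difference was -1.05 ± 0.38 (SD, n = 3), below 0 in 3 of 3 replicates (two-sided permutation over 30 combinations, adjusted p = 0.00915). Of the combinations with Tnfrsf4, 10 of 15 lay below the non-targeting mean, against 2 of 15 without it, and their constructs were detected in 18 of 270 cases against 32 of 270. Zap70 had the largest difference, -1.22, and did not pass (exact permutation over 15 combinations, adjusted p = 0.131). Among the checkpoint genes, Pdcd1 (0.66, adjusted p = 0.30) and Adora2a (0.56, adjusted p = 0.430) were highest, followed by Ctla4 (0.086), Havcr2 (-0.16), Tigit (-0.31) and Btla (-0.41), none past the permutation test. Cd28 (0.33), Il2ra (0.049), Tnfrsf9 (0.0067), Tnfrsf18 (-0.11), Cd3e (0.60), Lat (0.48) and Cd247 (0.044) did not pass either. The Tnfrsf4 call was lost without replicate 1 (-1.11, adjusted p = 0.0669), without replicate 3 (-0.85, adjusted p = 0.194) and with medians over constructs (-0.29, adjusted p = 0.477).

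**Figure D4:**
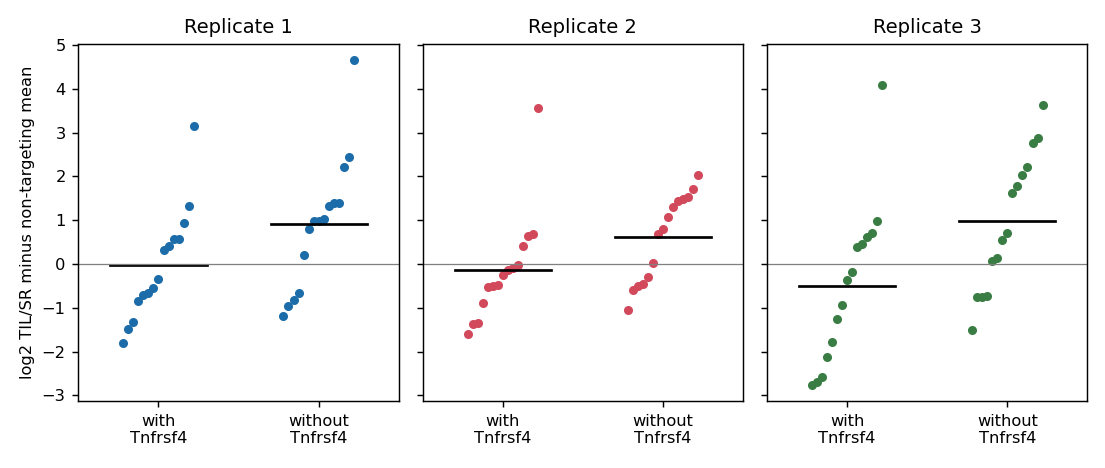
Log2 TIL/SR minus the non-targeting mean of the 30 co-stimulatory combinations, 15 with and 15 without Tnfrsf4, in each replicate; points are combinations and black lines their means. The mean with Tnfrsf4 is lower in all 3 replicates, with differences of -0.95, -0.74 and -1.47.

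The last comparison asked whether a combination exceeded what its single genes would give together, the question of synergy. None of 86 combinations of 2 or more genes differed from the sum of its single-gene values past limma, where 14 had an unadjusted p under 0.05, and none differed from its highest single gene, where 8 did. Values above the sum were highest for Ctla4+Tigit (3.07 ± 2.19, SE, n = 3), Btla+Tigit (2.77 ± 0.92), Adora2a+Btla+Ctla4 (2.74 ± 1.58), Adora2a+Ctla4+Pdcd1 (2.21 ± 1.02) and Btla+Ctla4+Tigit (2.09 ± 1.18), with limma adjusted p between 0.243 and 0.461. Below the sum lay Btla+Ctla4+Havcr2+Pdcd1 (-4.22 ± 1.09), Ctla4+Havcr2+Pdcd1 (-3.79 ± 1.23), Havcr2+Pdcd1 (-3.79 ± 1.22), Adora2a+Ctla4+Havcr2+Tigit (-3.74 ± 1.47) and Adora2a+Havcr2+Pdcd1 (-3.62 ± 1.30), with adjusted p between 0.207 and 0.243. The bootstrap over constructs gave no interval of the excess over the sum that excluded 0. Adora2a+Ctla4+Pdcd1 exceeded its highest single gene, Pdcd1, by 3.63 ± 0.68 (SE, n = 3; limma adjusted p = 0.137), and it was the 1 combination whose 95% bootstrap interval for that difference lay above 0 (0.28 to 6.86). Of the 86 intervals 4 excluded 0, against 4.3 by chance at this level. The interval lay below 0 for 3 combinations, named after their values were seen: Tnfrsf4+Tnfrsf9 (-3.40 to -0.052), Btla+Pdcd1 (-6.53 to -0.44) and Adora2a+Ctla4+Havcr2+Tigit (-5.05 to -0.34). When medians replaced means over constructs, 23 combinations passed for the sum and 23 for the highest single gene, and without replicate 3 these numbers were 20 and 24.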

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

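The share of constructs detected, the authors' log2 values, TIL 1 and TIL 2 averaged or as 1 library, single regions in the permutation test, and pseudocount 0.5, single regions and the lowest decile in the excess were chosen after seeing the data, as was the lowest decile for single constructs; the other alternatives were fixed before. The cause of the changes below was not tested. Over the named items, 459 values kept their direction and side of the threshold, 35 changed sign, 27 came past it and 35 no longer passed. A value that changed sign was counted only as such, even where it also came past the threshold. Adora2a+Ctla4+Pdcd1 passed the permutation test in 15 of 15 alternatives and limma in 7 of 12 (adjusted p up to 0.331), with values from 4.99 to 9.57 in limma. The alternatives built on raw counts (DESeq2 size factors and the DESeq2 test) were not run because the values are scaled and rounded. Between 61 and 97 constructs were detected per TIL replicate. In simulated sets matched to these numbers, but drawn independently for each replicate, limma called 40.9% of combinations raised 8-fold, 14.5% at 4-fold and 1.82% at 2-fold. At least 3 constructs of a combination were detected in 10 of 303 combinations by replicate, so medians over constructs mostly describe undetected constructs.

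With scaling on non-targeting constructs, 145 single constructs were lower and 32 higher; 5 were higher with region 1 only, and 7 to 28 without a replicate. Combinations higher under limma numbered 11 with medians (37 were lower), 2 with pseudocount 0.5 and with region 1 only, 0 with region 2 only, centring on all constructs or the authors' log2 values, and 0 to 10 without a replicate. Combinations past the permutation test numbered 6 with pseudocount 0.5, and 2 with medians, pseudocount 5, the lowest decile left out, region 2 only, the authors' log2 values, and detection with or without adjustment for starting abundance. They numbered 1 against all constructs and with TIL 1 and TIL 2 averaged or as 1 library, and 1 to 4 without a replicate. Targets past the test numbered 0 with medians and 0 to 1 without a replicate; the 1 without replicate 3 was Zap70. For the excess over the sum, 5 passed with region 1 only, 23 with medians and 0 to 20 without a replicate; over the highest single gene, 23 with medians and 0 to 24 without a replicate. Constructs up in every replicate numbered 0 at 3-fold, 26 when at least 2 of 3 replicates sufficed, and 5 to 20 without a replicate. The mean correlation of replicates was 0.40 with Spearman's and 0.16 with Pearson's coefficient.

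Whether the replicate numbers pair the samples stays open. Deviations of same-numbered SR and TIL samples correlated at 0.075, -0.082 and 0.086, and not every sample correlated best with its own number. These correlations cannot decide it, because SR levels of different replicates correlated at 0.96 to 0.99 and TIL levels at only 0.094 to 0.45. The authors' ratios set each TIL library beside an SR library. With the replicate number as a block, 4 combinations were higher under limma, against 1 without it, the others being Adora2a+Ctla4+Havcr2+Pdcd1, Adora2a+Btla+Ctla4 and Ctla4+Tigit; the 467 lower and 3 higher single constructs and the 0 excesses were the same numbers with the block.

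The median shift of the checkpoint class was -0.046 with region 1 only, -0.045 without the lowest decile and -0.024 to 0.071 without a replicate. With means in place of medians the shift was 0.31 for co-stimulatory and 0.19 for TCR signalling constructs. The detection difference was 5.65 points for checkpoint and -0.67 points for TCR signalling constructs beyond starting abundance, 6.01 points for co-stimulatory constructs in either region (now past the permutation test, adjusted p = 0.0400), and 7.14 to 9.08 points for checkpoint without a replicate. Spearman's coefficient with the number of targets was -0.0095 to 0.17 for checkpoint without a replicate and 0.059 for co-stimulatory with medians. For TCR signalling it was 0.24 with medians, 0.019 without the lowest decile and -0.20 to 0.10 without a replicate.

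The Tnfrsf4 difference between combinations with and without it was -0.29 with medians and -1.21 to -0.85 without a replicate. Differences that changed sign without the lowest decile were Havcr2 (0.067), Tnfrsf9 (-0.20) and Cd247 (-0.16), and with the authors' values Tnfrsf9 (-0.032). Without a replicate they ran from -0.18 to 0.25 for Ctla4, -0.36 to 0.061 for Havcr2, -0.49 to 0.48 for Il2ra, -0.11 to 0.11 for Tnfrsf9, -0.56 to 0.14 for Tnfrsf18 and -0.17 to 0.38 for Cd247.

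Single genes against non-targeting constructs changed sign with medians for Btla (0.19), Havcr2 (-0.35), Adora2a (-0.27), Cd28 (-0.28), Tnfrsf9 (-0.50), Cd3e (-0.42) and Lat (-1.01), as did the excess of Adora2a+Ctla4+Havcr2+Tigit (0.63). Centring on all constructs gave -0.54 for Tnfrsf9, -0.31 for Tnfrsf18, -0.044 for Cd247 and -0.18 for Cd3e. Tnfrsf4 was 0.064 with pseudocount 0.5 and 0.16 without the lowest decile, Tnfrsf9 -0.13 with pseudocount 5 and -0.48 with region 2 only, and Cd247 -0.031 with region 1 only. Without a replicate the values ran from -0.35 to 1.36 for Ctla4, -0.46 to 0.51 for Tnfrsf4, -0.27 to 0.50 for Tnfrsf9, -0.23 to 0.76 for Tnfrsf18, -0.32 to 1.07 for Cd3e and -0.21 to 1.48 for Lat.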

Other observations

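The tests in this part were chosen after the results were seen, except those of carry-over between libraries and of starting abundance and single combinations for Tnfrsf4. Among the TCR signalling combinations, Cd247+Cd3e+Lat had the highest value, 2.73 ± 0.80 (SE, n = 3) relative to non-targeting constructs, above them in 3 of 3 replicates. It did not pass limma (adjusted p = 0.153) or the permutation test (adjusted p = 0.113), and its constructs were detected in 6 of 18 cases. Cd247+Cd3e+Lat+Zap70, which adds the kinase gene Zap70, was detected in 0 of 15 cases; the difference between both combinations was not tested. Besides the Il2ra and Adora2a+Btla+Havcr2 constructs, 4 constructs were detected in all 3 replicates. They target Tnfrsf18+Tnfrsf9, Havcr2+Tigit, Adora2a+Pdcd1 and Adora2a+Ctla4+Havcr2+Pdcd1, with log2 changes of 1.25 ± 0.62, 0.78 ± 1.04, 0.48 ± 0.74 and 0.097 ± 0.21 (SE, n = 3), none past limma. Scaled on the non-targeting constructs all 4 passed it, with log2 changes of up to 9.65 above these (limma adjusted p = 0.0131, 0.0256, 0.0164 and 0.00282). These 4 were chosen for detection in all 3 replicates, while non-targeting constructs were detected in 16 of 252 cases. The pass under this scaling therefore follows largely from that choice.

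TIL 1 and TIL 2 shared 29 detected constructs, against 6.91 for independent lists, while TIL 1 and TIL 3 shared 18 and TIL 2 and TIL 3 shared 14, against 16.9 and 12.9 when shuffled within starting abundance. Shuffling TIL 2 among constructs of similar starting abundance gave 9.07 shared constructs on average (95% range 4 to 14). Shuffling within combinations gave 12.3 (8 to 17). These values argue against starting abundance, or a gene effect equal for all constructs of a combination, as the whole source. A gene effect that differs between the constructs of a combination was not tested, and the shuffles were not combined. Carry-over of material between the libraries would bring the most abundant constructs along, but 12 of the 20 most abundant of TIL 1 were not detected in TIL 2 and 10 of the 20 of TIL 2 not in TIL 1. The 12 were not absent: in region 1 of TIL 2 their median was 167.5 scaled reads, against 2 for constructs undetected in both, and 0.0463% of their TIL 1 level (highest 187%), while shared constructs had at least 5.74%, so carry-over of a small amount from TIL 1 stays open though not as the whole source. Cells of the same clones transferred for both pools may have contributed, which was not tested.

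For Adora2a+Ctla4+Pdcd1, detection beyond that predicted from starting abundance had a permutation adjusted p = 0.00101, the smallest these permutations can give. With each of its 6 constructs left out in turn, the difference from non-targeting constructs stayed between 5.93 and 6.74 and the highest permutation p was 1.0e-05, the smallest the permutations can give. Without its 2 constructs detected in both TIL 1 and TIL 2 the other 4 differed by 6.17 (permutation p = 2.0e-05); none of the 84 non-targeting constructs was detected in both. These values argue against starting abundance, a single construct or constructs shared by TIL 1 and TIL 2 as the whole source. A candidate explanation is that joint loss of Adora2a, Ctla4 and Pdcd1 favours CD8+ T cells in these tumours; the excess over the single genes did not pass limma, so synergy stays open.

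For Tnfrsf4, the difference in detection between combinations with and without it, beyond starting abundance, was -4.54 points (permutation p = 0.0335, not adjusted over the targets), and with each of the 30 combinations left out in turn the difference lay between -1.18 and -0.96 (highest permutation p = 0.00156). Over TIL 1 and TIL 2 alone it was -0.85 with an unadjusted permutation p = 0.0380, but 0.194 after adjustment over 15 targets. These values argue against a single combination as the whole source. Starting abundance stays open, because the p of its test was not adjusted over the 15 targets from which Tnfrsf4 was picked. TIL 3 as the source stays open too. No biological explanation was tested beyond the comparison of combinations with and without Tnfrsf4.

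The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 470 constructs past limma and the highest other split 0; for combinations the real split gave 1 and the highest other split 0. For the excess over the sum all 10 splits gave 0 by limma, where the real split had 14 combinations at an unadjusted p under 0.05.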
